A study of Mus musculus with 12 samples.

How the data were processed

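Nrf2 occupancy was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in mouse peritoneal macrophages. Per the labels' protocols, mice received 4% thioglycolate broth into the peritoneum, an irritant that draws macrophages into the cavity, and the cells were collected 4 days later, cultured, and treated with diethyl maleate at 100 µM for 4 hours. Proteins were cross-linked to DNA with formaldehyde (1%, 10 min) and chromatin was precipitated with an anti-Nrf2 antibody. The 12 samples form 4 groups of 3: ChIP and input libraries of wild-type (WT) and of Nrf2 AY/AY (AY) macrophages. Peak lists of the 6 ChIP libraries were analysed; values of the 6 input libraries were not analysed here, so no background library could be set beside the peaks.

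Per the submitters' processing notes, bcl2fastq 2.15.0, Bowtie2 and MACS 1.4 were used and the genome build was mm9; the roles and settings of these tools, the Bowtie2 version, the handling of duplicate reads and whether each input served as the control of its ChIP library are not given in the sources used here. The authors deposited 1 list per ChIP library, so peaks were called per library and not on pooled libraries. Each list has 5 columns without a header: chromosome, start, end, a peak name of the MACS form, and a score. The deposited score is each peak's own value from the authors' peak caller. No score lies below 50 and the highest is 3100, reached by 1 peak in each of 3 libraries. The score was therefore read as -10 log10 of the peak's p-value, so that 50 corresponds to a p-value of 1e-05 and 100 to 1e-10. Scores were used only to rank or filter peaks within a list, since they move with read depth and with the control. The lists give no read counts, so the depth of every library is unknown; a shallower library yields fewer peaks, and a missing peak shows only that a site did not pass the caller's threshold in that library.

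Coordinates are mm9, printed counting from 1. A gene table at hand is on GRCm38, a different build, and no genome sequence was used. Regions are therefore named by position only, and the planned comparisons of binding motifs and of gene lists near peaks were not made.

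The peaks of all libraries were merged into union regions where they overlapped by at least 1 bp, and a library was taken to hold a region if at least 1 of its peaks lay in it. Regions were called WT-restricted with a peak in 3 of 3 WT and 0 of 3 AY libraries, and AY-restricted in the reverse case. For each pair of libraries, the share in common was the number of regions held by both divided by the number held by either (the Jaccard index). Differences of genotype means were tested with two-sided exact permutation tests over the 20 assignments of labels, which cannot give a p below 0.1. The excess of the share in common within genotypes over that between genotypes was tested one-sided over the 10 distinct splits of 3 against 3 libraries, where the smallest p is also 0.1. For a single region, presence in 3 libraries against absence in 3 cannot reach a two-sided Fisher exact p below 0.1, so regions were counted and not tested one by one. The labels give each library an identifying number of its own but do not say that the libraries came from separate animals, so the p-values measure only the spread between these libraries, which may be technical.

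The named regions follow a rule fixed before the data were examined. They are the 10 regions in all 6 libraries, the 10 WT-restricted and the 10 AY-restricted regions with the best mean relative rank, which is the rank of the score within a list divided by the length of that list, averaged over the libraries that hold the region. Alternatives fixed at the same time were a score of at least 100, the same number of top-scoring peaks from every library (826, the length of the shortest list), the numbered chromosomes and X only, each library left out in turn, both libraries numbered 3 left out, an overlap of 50% of the shorter peak, base pairs in place of regions, and the replicate number as a block. Merging of peaks up to 1 kb apart, the numbered chromosomes alone, and leaving out 1 Mb bins in which a library holds 5 or more peaks were added after the data were seen. No peak list and no peak on random or unplaced sequence was left out of the main values.

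The counting of regions was tested on simulated data. With 200 shared, 300 AY-restricted and 150 WT-restricted sites and complete detection, the counts returned were 200, 300 and 150. With each site detected in a library with a chance of 80%, 167 AY-restricted and 81 WT-restricted regions were returned. With 600 sites common to all libraries, each detected with a chance of 70%, and no restricted site, 3 AY-restricted and 11 WT-restricted regions arose from missed detection alone. Detection was independent there, with the same chance for every site and library, whereas the real lists differ in length. These counts thus do not show how many restricted regions missed detection could give in the real lists. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.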

Results

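Sites bound by Nrf2, the transcription factor that controls the response to electrophilic and oxidative stress, were mapped in thioglycolate-elicited peritoneal macrophages of 2 genotypes. WT cells carried the normal Nrf2 gene and AY cells were homozygous for an allele named Nrf2 AY, which is known as an alanine-to-tyrosine change in the part of the protein that contacts DNA. All cells had been exposed to 100 µM diethyl maleate, an electrophile that stabilises Nrf2, for 4 hours. The comparison asked how the chromatin sites occupied by the mutant protein relate to those of the wild-type protein under this stress. Each genotype was represented by 3 ChIP libraries. The 6 peak lists together held 8644 peaks, which merged into 4147 regions of the mm9 genome. The read depth behind the lists is unknown.

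The number of Nrf2 peaks did not separate the genotypes. WT libraries held 1604, 826 and 1533 peaks (replicates 1, 2 and 3), and AY libraries held 2154, 1441 and 1086. The means were 1321 ± 430 in WT and 1560 ± 544 in AY (SD, n = 3 each), a difference of 239 peaks that was smaller than the spread within either genotype (exact permutation p = 0.6, two-sided). The difference changed sign without AY replicate 1, to -57.5 peaks, and without WT replicate 2, to -8.17 peaks. The median peak width was 551 ± 44.5 bp in WT and 586 ± 74.5 bp in AY libraries (SD, n = 3; exact permutation p = 0.6).

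**Figure D1:**
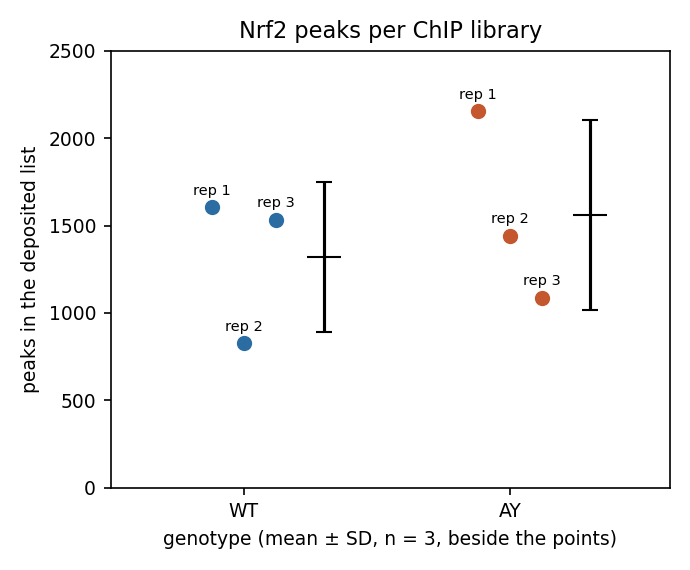
Number of peaks in the deposited list of each Nrf2 ChIP library (vertical axis) by genotype (horizontal axis). Each point is 1 library, and the bar beside the points gives the mean ± SD of 3 libraries, 1321 ± 430 in WT and 1560 ± 544 in AY.

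The positions of the peaks did separate the genotypes. Pairs of WT libraries had 38.5% of their regions in common on average (34.2% to 44.8%, 3 pairs), and pairs of AY libraries 42.2% (34.9% to 49.0%, 3 pairs). A WT and an AY library had 16.4% in common (15.2% to 19.6%, 9 pairs). Each of the 6 pairs of 1 genotype thus exceeded each of the 9 mixed pairs. The mean was 40.4% within genotypes and 16.4% between them, a difference of 24.0 percentage points, and no other split of the 6 libraries gave a difference as large (exact permutation p = 0.1, one-sided, the smallest that 10 splits allow). The overlap between genotypes was itself far above the level of unrelated positions. Of 2313 regions merged from the WT lists, 792 overlapped a region of the AY lists, whereas 8 to 50 did so after the AY regions had been moved by 10 to 100 kb in either direction.

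**Figure D2:**
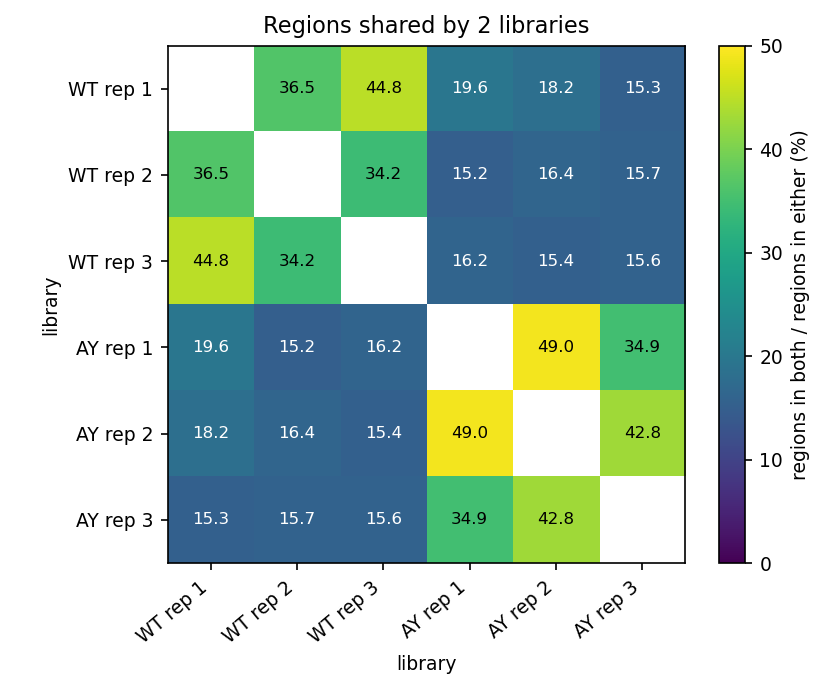
Share of regions in common for each pair of libraries, as regions held by both libraries divided by regions held by either (colour and number, %). Both axes list the 6 libraries. The pairs of 1 genotype lie between 34.2% and 49.0% and the mixed pairs between 15.2% and 19.6%.

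Of the 2099 regions found in 2 or more libraries, most were seen in 1 genotype only, and the rest held peaks of both. A peak was present in at least 2 of 3 libraries at 1068 regions in WT and at 1309 regions in AY, and 395 regions met this in both genotypes, which is 37.0% of the WT and 30.2% of the AY set. At 524 regions at least 2 WT libraries and no AY library held a peak, and at 805 regions at least 2 AY libraries and no WT library did. The other 375 regions were mixtures with a peak in 1 library of at least 1 genotype and in 1 to 3 of the other. Of all regions, 2048 (49.4%) were seen in 1 library only. These formed 27.5%, 16.2% and 28.3% of the regions of WT replicates 1, 2 and 3, and 32.0%, 14.3% and 14.7% of those of AY replicates 1, 2 and 3.

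Nrf2 peaks were present in all 6 libraries at 202 regions, 35.7% of the 566 regions found in every WT library and 27.7% of the 730 found in every AY library. The first by mean rank was chromosome 10, 67175526 to 67176537. It ranked 5, 3 and 6 by score in WT replicates 1, 2 and 3 and 1, 2 and 2 in AY replicates 1, 2 and 3. The second, chromosome 3, 50241592 to 50242696, ranked 2 in each WT list and 8, 5 and 4 in the AY lists. A region on chromosome 2, 151930666 to 151931723, ranked between 8 and 16 in every list. On chromosome 4, 116355287 to 116356368 ranked 3, 7 and 3 in WT and 28, 20 and 27 in AY. The other 6 regions named by the rule lay on chromosome 9 (82873705 to 82874718), chromosome 6 (115616235 to 115617337), chromosome 4 (11015494 to 11016508 and 148544443 to 148545494), chromosome 7 (52715824 to 52716829) and chromosome 17 (43694436 to 43695446). These 6 ranked between 5 and 66 in every list. The 202 regions had a median width of 899 bp and lay on all 19 autosomes, with 2 on X and none on Y or on random sequence. The count fell to 100 when only peaks with a score of at least 100 were used and to 133 when all lists were of equal length.

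WT-restricted binding was found at 216 regions, 38.2% of those held by every WT library. The strongest by rank was chromosome 15, 53246089 to 53247120, which ranked 12, 5 and 9 in WT replicates 1, 2 and 3 and had no peak in any AY list. Chromosome 5, 53776674 to 53777709, ranked 22, 22 and 26, and chromosome 11, 103821525 to 103822402, ranked 27, 29 and 35. On chromosome 17, 3195151 to 3196127 ranked 45, 35 and 86. Chromosome 8 held 2 of the named regions, 10682798 to 10683776 (ranks 61, 64 and 48) and 35877922 to 35878766 (ranks 75, 61 and 45). The remaining 4 were on chromosome 12 (109852914 to 109853782), chromosome 13 (110566160 to 110566962), chromosome 9 (120739479 to 120740389) and chromosome 11 (53901546 to 53902349), with ranks from 39 to 104. The set had a median width of 724.5 bp and was spread over the 19 autosomes with 5 to 20 regions on each, and none lay on X, Y or random sequence. Of the libraries left out in turn, WT replicate 2, the shortest list, moved the count most. Without it, 469 regions were held by both other WT libraries and by no AY library, which is a looser rule. With a score of at least 100, 134 regions were WT-restricted.

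AY-restricted binding was found at 389 regions, 53.3% of those held by every AY library. The first by rank was chromosome 7, 110910356 to 110912391, the widest AY-restricted region at 2036 bp, which ranked 3, 8 and 31 in AY replicates 1, 2 and 3 and had no peak in any WT list. Chromosome 12, 60081788 to 60082759, ranked 24, 22 and 19, and chromosome 15, 59033629 to 59034440, ranked 38, 31 and 34. On chromosome 5, 21301371 to 21302338 ranked 22, 19 and 60, and on chromosome 18, 67877615 to 67878177 ranked 82, 65 and 25. The other 5 named regions were on chromosome 3 (27108489 to 27109826), chromosome 9 (50884871 to 50885759), chromosome 12 (101353916 to 101354913), chromosome 16 (92399946 to 92400847) and chromosome 6 (88003504 to 88004438), with ranks from 26 to 172. The set had a median width of 771 bp, with 9 to 33 regions on each of the 19 autosomes, 5 on X, 1 on random sequence of chromosome 8 and none on Y. Here the count depended on AY replicate 3, the shortest AY list, and on the score, with 220 regions at a score of at least 100. AY-restricted regions were 1.80 times as many as WT-restricted ones, but this ratio rested on the shortest list of each genotype. It turned to 0.834 without WT replicate 2 (391 AY-restricted and 469 WT-restricted regions) and rose to 3.28 without AY replicate 3 (715 and 218), and the difference between the counts was not tested.

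No other set of 3 libraries came near these counts. The other 18 sets of 3, which mix the genotypes, had 0 to 49 regions held by their 3 libraries and by none of the rest, with a median of 2. The highest, 49, belonged to WT replicates 1 and 3 with AY replicate 1, the 3 longest lists. With the 826 top-scoring peaks of each library, so that all lists were of 1 length, 219 regions were WT-restricted, 307 were AY-restricted and 133 were found in all 6 libraries. Such a region may have had a lower-scoring peak of the other genotype that was cut from the list.

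**Figure D3:**
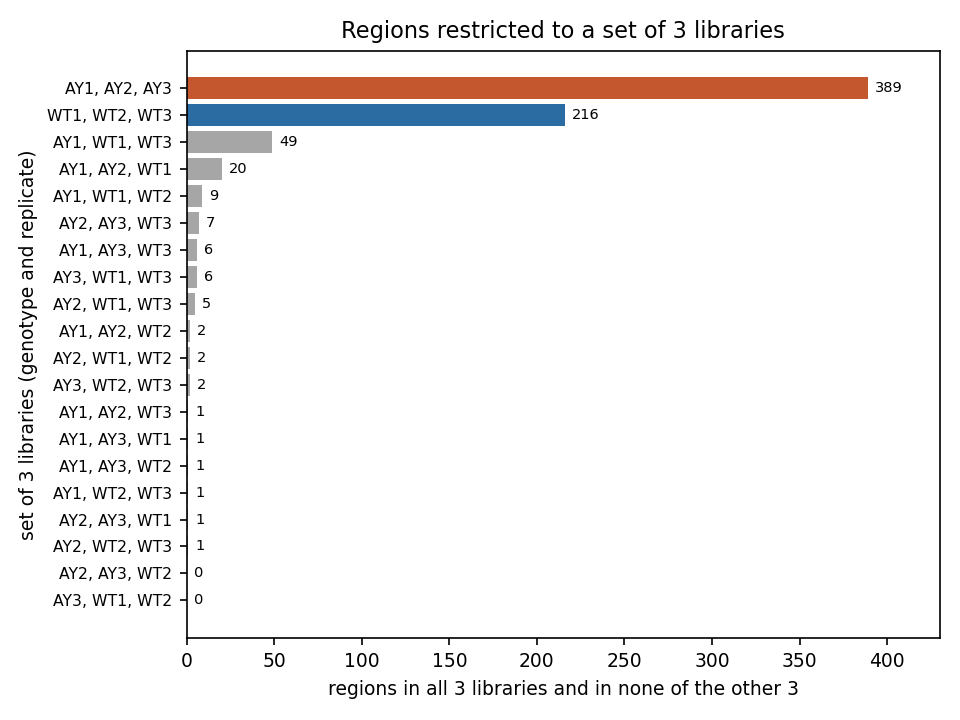
Number of regions held by all 3 libraries of a set and by none of the other 3 (horizontal axis), for each of the 20 sets of 3 libraries (vertical axis; WT1 stands for WT replicate 1, and so on). The AY set holds 389 and the WT set 216, and the mixed sets, in grey, hold 0 to 49.

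The highest-scoring peaks of every list lay mostly in regions found in all 6 libraries, and a smaller part lay in genotype-restricted regions. Of the 100 highest-scoring peaks, 17 in each WT library lay in WT-restricted regions, and 15, 17 and 21 in AY replicates 1, 2 and 3 lay in AY-restricted regions. Regions found in all 6 libraries took 70, 67 and 58 of the 100 in WT replicates 1, 2 and 3, and 59, 52 and 53 in AY replicates 1, 2 and 3. Over the whole lists, regions found in all 6 libraries took 9.38% to 24.5% of the peaks. Restricted regions took 13.5%, 26.3% and 14.1% of the whole lists of WT replicates 1, 2 and 3 and 18.1%, 27.1% and 35.9% of those of AY replicates 1, 2 and 3. Their share of the 100 highest-scoring peaks was thus below their share of the list in WT replicate 2 and the 3 AY libraries, and above it in WT replicates 1 and 3. At most 1 of the 100 was seen in its own library only. Among the 100 lowest-scoring peaks, 45 to 81 were in their own library only, 0 to 6 lay in regions found in all 6 libraries and 0 to 19 in regions restricted to the genotype, with 19 in AY replicate 3 and 14 in WT replicate 2, the shortest list of each genotype.

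**Figure D4:**
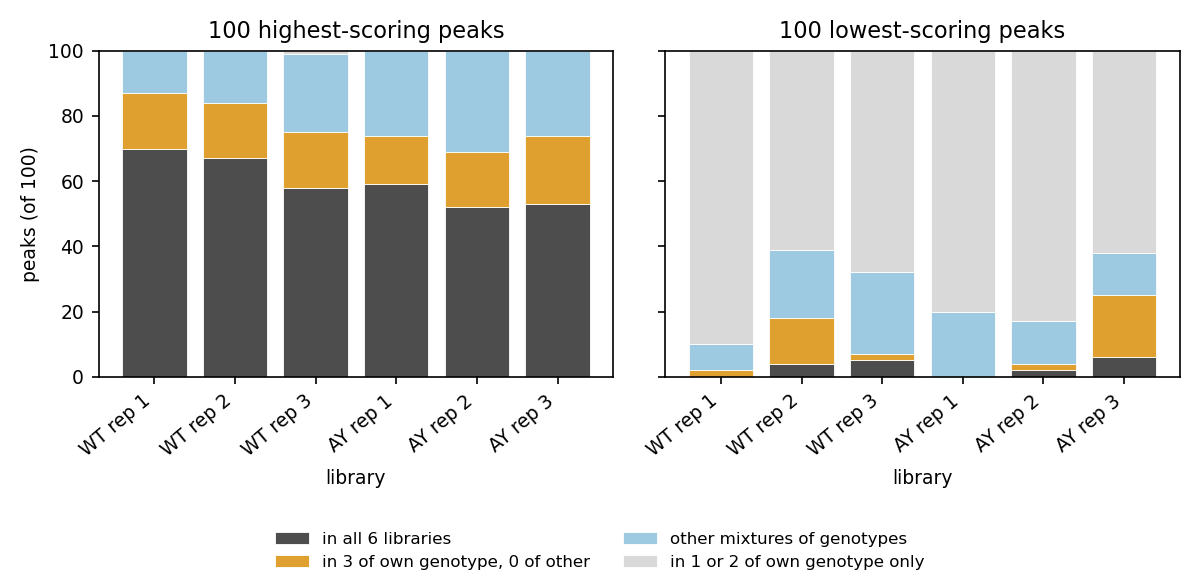
Classes of the 100 highest-scoring (left) and 100 lowest-scoring (right) peaks of each library, as stacked numbers of peaks out of 100. Among the highest-scoring peaks, 52 to 70 lie in regions found in all 6 libraries and 15 to 21 in regions found in the 3 libraries of the same genotype only.

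Peaks on the sex chromosomes differed between libraries of 1 genotype. WT replicates 1 and 3 had no peak on Y or its random sequence, whereas WT replicate 2 had 18 and AY replicates 1, 2 and 3 had 15, 27 and 20. On X, WT replicates 1, 2 and 3 had 46, 12 and 121 peaks, and AY replicates 1, 2 and 3 had 29, 29 and 24. As a share of the list, X peaks were 4.07% ± 3.38 in WT and 1.86% ± 0.453 in AY (SD, n = 3; exact permutation p = 0.3, two-sided). The WT mean rested largely on WT replicate 3, at 7.89%, and was 2.16% without it. WT replicate 1, which also had no Y peak, had the next highest share, 2.87%. The libraries with Y peaks had 1.35% to 2.21%, with WT replicate 2 at 1.45%. WT replicate 3 also held 250 peaks, 16.3% of its list, in 15 bins of 1 Mb in which it had over 2 times the peaks of any other library, and none of these lay in a WT-restricted region. Without WT replicate 3, 255 regions were held by both other WT libraries and no AY library, and 404 by the 3 AY libraries and neither other WT library. Fewer libraries have to hold or lack a region there, so higher counts follow from the rule and do not test the influence of WT replicate 3. On the numbered chromosomes alone, 216 regions were WT-restricted, 383 were AY-restricted and 200 were found in all 6 libraries.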

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

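The alternatives with merging of peaks up to 1 kb apart, with numbered chromosomes alone and without bins dense in peaks were chosen after the data were seen. The excess of the share in common within genotypes over that between genotypes kept its direction in all 15 alternatives run, between 19.5 percentage points (base pairs in place of regions) and 35.1 (the same number of top peaks per library). The test cannot pass 0.05 in any of them. With a score of at least 100, 100 regions were found in all 6 libraries, 134 were WT-restricted and 220 AY-restricted; the shorter lists account for part of each fall by construction. With equal lists, 133 were found in all 6, while the restricted counts stayed within 1.5 times their main values. Both settings drop called peaks, so a region can become restricted when its peak in the other genotype is dropped. Leaving out each library in turn gave 218 to 469 WT-restricted regions, the highest without WT replicate 2, and 391 to 715 AY-restricted regions, the highest without AY replicate 3; fewer libraries have to hold or lack a region in these counts. The ratio of AY- to WT-restricted regions, 1.80, reversed to 0.834 without WT replicate 2, where 2 WT but 3 AY libraries had to hold a region. Without both libraries numbered 3, 731 regions were AY-restricted. The difference in peak number ranged from -57.5 to 476.5 when a library was left out, reversing without AY replicate 1 and without WT replicate 2 (-8.17). With the replicate number as a block it was 239 peaks with an exact sign-flip p of 0.5, where 0.25 is the smallest possible. The numbers were not taken to pair the libraries. Over regions held by 2 to 5 libraries, the deviations from the genotype means of same-numbered libraries correlated at 0.096, 0.086 and 0.195 (numbers 1, 2 and 3), although each library correlated best with its own number, a hint from the data and not from the design. Settings for motifs and gene lists (motif form, search window, distance to a gene start) were not run, because no sequence or annotation of mm9 was used. Unknown read depth limits every absence of a peak.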

Other observations

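Apart from the equal lists, which were fixed before the data were examined, the tests in this part were chosen after the peak overlaps had been seen, and those for chance splits, for the score threshold, for the sex of the mice, for neighbouring libraries and for the clusters in WT replicate 3 after the values they measure were known. Among the 202 regions present in all 6 libraries, the order of the scores differed by genotype. The regions were ranked within each list from 1, the highest score, to 202. Spearman's rho across these regions, which are not independent replicates, was 0.821 to 0.893 in the 6 pairs of libraries of 1 genotype and 0.206 to 0.281 in the 9 mixed pairs (mean difference 0.607). Ranks of the 3 WT and 3 AY libraries did not overlap at 122 regions (60.4%, where chance gives 10%), with 57 ranked higher in AY and 65 higher in WT. The regions named next were picked from these 122 for their large differences in mean rank, so they are extremes. On chromosome 6, 5157568 to 5158487 had a mean rank of 170 ± 20.3 in WT and 3 ± 1 in AY (SD, n = 3). On chromosome 1, 163825969 to 163826927 had 18.7 ± 11.7 in WT and 194 ± 6.25 in AY. On chromosome 10, 2 regions near each other went opposite ways: 87294600 to 87295453 had 190 ± 6.51 in WT and 28 ± 5.29 in AY, and 87304967 to 87305896 had 35.3 ± 7.09 in WT and 181 ± 9.45 in AY. The real split was the 1 of the 10 splits with most regions of separated ranks, 122 against at most 17 in the others, and 10 splits are too few for a share under 0.05. The lowest rho of a same-genotype pair was 0.821 and the highest of a mixed pair 0.281. That gap fits a hypothesis that the AY change may alter the relative occupancy of sites that both proteins bind. A difference in strain background or library handling that follows genotype could give it as well. How far the requirement of a peak in every list lowers the rho of mixed pairs was not tested.

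Genotype-restricted regions lay near regions found in all 6 libraries more often than shifted positions did. Of the 389 AY-restricted regions, 32 were within 50 kb of a region that was WT-restricted or found in all 6 libraries, against 3 to 12 in the middle 96 of 100 sets in which each region was moved by 1 to 5 Mb. Most of this came from regions found in all 6 libraries, with 27 AY-restricted regions within 50 kb (shifted sets 1 to 8), and 11 of the 216 WT-restricted regions also lay that near (shifted sets 0 to 4). AY-restricted and WT-restricted regions were within 50 kb of each other in 6 cases, inside the shifted range of 1 to 8, but within 200 kb in 42 cases (shifted sets 7 to 21). A general pull of peaks to the same active loci would give regions seen in 1 AY library the same nearness to the common regions. These had 3.52% within 50 kb (37 of 1051, against 3 to 15 in the middle 96 of 100 shifted sets), so they too lay nearer than shifted positions, but less often than the 6.94% of AY-restricted regions (Fisher's exact p = 0.00884 across regions, two-sided). The comparison cannot decide on a general pull, because peaks seen once include many of the weakest calls. Any false calls among them would lower their share even under such a pull. In WT, 2.01% of regions seen in 1 library and 5.09% of WT-restricted regions lay that near (Fisher's exact p = 0.0155 across regions, two-sided). A hypothesis in which both proteins act at some of the same loci through different elements could also give the 32 regions. They do not single it out, since most lay near regions found in all 6 libraries. Nearness of AY-restricted to WT-restricted regions exceeded the shifted range within 200 kb but not within 50 kb. Without mm9 genes or sequence the hypothesis remains open.

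The 605 genotype-restricted regions were weighed against technical explanations. With equal lists of 826 peaks the total was 526, against at most 7 in the other 9 splits, which argues against unequal list length as the source of the grouping by genotype. The size of the 526 is less certain. Cutting the lists drops called peaks, so some regions count as restricted only because a peak of the other genotype was cut. At least 15 of the 100 highest-scoring peaks of every library were restricted to its genotype, which argues against calls near the score threshold as the whole cause; it leaves them open for lower-scoring regions, since the restricted share of these top peaks was below that of the whole list in 4 of the 6 libraries. WT replicate 2 has peaks on Y as the AY libraries do, yet had at least 34.2% of its regions in common with each other WT library and at most 16.4% with an AY library, against the sex of the mice as the cause; and WT replicate 3 and AY replicate 3, whose identifying numbers are adjacent, had 15.6% in common, below the 34.2% or more that each had with libraries of its own genotype. The real split was the 1 of the 10 splits with most restricted regions, 605 against at most 49 in the others, and 10 splits are too few for a share under 0.05; a genotype difference, or one in strain background or library handling that follows genotype, may account for the pattern and was not tested further.

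WT replicate 3 held dense local clusters of peaks. In 15 bins of 1 Mb it had 5 or more peaks and over 2 times as many as any other library, 250 peaks or 16.3% of its list, of which 196 were in no other library and 0 in WT-restricted regions; 86 lay on chromosome 4 between 145000001 and 148000000, and 80 on X. Outside X, WT replicate 1, which also lacks Y peaks, had 11 peaks in these bins. The libraries with Y peaks had 9 to 40 there, with 40 in AY replicate 3. On X, WT replicate 1 had 10 and a library with Y peaks had at most 6. The bins were chosen because WT replicate 3 exceeded every other library in them, WT replicate 1 included. These counts therefore cannot decide on the sex of the mice. Outside X, those 40 peaks of AY replicate 3 were 3.68% of its list. The 4 remaining lists together had 0.896% (Fisher's exact p = 1.56e-10, across peaks, which are not replicates). The highest of them, AY replicate 2 with 24 peaks, had 1.67%. A batch shared by the libraries numbered 3 could give this, although no batch is labelled. The p-value measures counting error in 1 library and not the spread between libraries, so it cannot decide on a batch. On X, AY replicate 3 had 5 peaks, 0.460% of its list against 0.349% (p = 0.582, Fisher's exact), too few to decide. Duplicated or repeated sequence counted unequally stays open as well, since the share of 16.3% says nothing of the sequence in these bins. Apart from sex, no biological explanation was tested.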
